A study of Rattus norvegicus with 48 samples.

How the data were processed

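Deposited expression values of 48 Affymetrix rat expression arrays were used. They came from total RNA of rat pancreatic islets, extracted with Trizol and amplified with the Affymetrix 3' IVT Express kit per the labels. The deposited values were on a log2 scale, read from their range of 1.49 to 13.98, because the authors' unit and normalisation method were not given in the sources used here. The labels name Partek without a version. Array medians lay between 5.43 and 5.48, and no further normalisation was applied. Raw intensity files were not used here.

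The series holds 4 strains on 4 days of age. Per the labels each strain and day was 1 RNA pool of islets from 6 to 8 rats, hybridized to 3 arrays as technical replicates. The 3 arrays were averaged, and the 16 pools were the independent units, with 4 pools per strain and 8 pools per background. Replicate numbers did not pair arrays across pools, since residuals of arrays with the same number had a median correlation of 0.022 and those with different numbers -0.011. The sex mix of the pools, the scan dates and the breeding scheme of the F344 strains were not given in the sources used here.

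Of 31099 probe sets, 57 were controls, 20826 had 1 gene symbol, 436 had several and 9780 had none. Probe sets with 1 symbol were kept. For the 4525 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene, giving 14217 genes. Genes whose highest pool mean exceeded the 40th percentile of all values (4.76) were tested, which left 10927 genes.

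Differences were tested with limma 3.58.1 in R 4.3.3, with p adjusted by Benjamini and Hochberg and adjusted p under 0.05 taken as passing. Strain and day were additive terms on 16 pools for the comparison of old pools (days 40 and 50) with young pools (days 20 and 30), of BB with F344, of lyp/lyp with +/+ inside each background, and of these lyp effects with each other. The departure of the DRlyp/lyp day 50 pool was its own coefficient added to these terms. Slopes per 10 days were fitted per strain, and the DRlyp/lyp slope was compared with the mean of the other 3. Comparisons of lyp/lyp with +/+ on a single day had 1 pool per group. These used the 3 arrays per pool with passing set at adjusted p under 0.05 and an absolute log2 difference of at least 1, so their p measures array spread and not spread between rats. The STEM clustering named in the labels was not run.

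Gene lists were written from general knowledge before the data were examined, 29 in all. The camera test of limma with a preset correlation of 0.01 was applied to the 26 lists with at least 5 measured members, and 3 smaller lists were only counted. A camera test with the correlation estimated from the residuals is given beside each list in the results, and made 119 of the list results weaker while 4 stayed the same. List counts are also given with p adjusted over the list alone. A list shift is against the other genes tested and is relative.

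Genes were named by a rule set before the data were examined. For each comparison on pools these were the 6 genes per direction with the largest difference among those passing, for group comparisons only genes with the same sign on each day or in each strain. For single days they were 3 per direction. Added to these were the 3 members with the smallest p of each list passing in camera, 5 Gimap genes, Ccl11, Ins1, Ins2, Gcg and Sst. Genes from outside this rule are said to be chosen after their values were seen. Where the lower of the compared groups had a mean below the filter value, the fold is given as a lower bound with values below the filter set to it, a choice made after the data were seen because no background level was given in the sources used here. No fold is given where both groups lay below it. Ccl11 lay below the expression filter and was tested without it.

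Alternatives planned before the data were examined were no filter, a filter on the mean over all arrays at the median, each array centred on its median, every probe set instead of 1 per gene, an intensity trend with robust prior, the pool as a random effect with the replicate number as block, all 48 arrays as if independent, leaving out each pool and leaving out each replicate number. Leaving out both BB day 50 pools, and giving the DR+/+ day 50 pool its own coefficient, were chosen after the data were seen. Other assignments of pools to groups were tried, up to 100 drawn per comparison. For single days, with 1 pool per group, technical arrays were reassigned instead.

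On simulated data with 200 changed genes (100 per effect size), limma recovered 86 of 100 genes at a log2 difference of 0.5 and 96 at 1 for the lyp effect in BB, and 61 and 93 for the departure. For the day 50 comparison of lyp/lyp with +/+ in BB it recovered 5 and 42, with 59 false calls. Among 49 named calls, 65 other probe sets could be compared, of which 8 had the opposite sign and 1 passed in the opposite direction. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.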

Results

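Islet gene expression was measured in 4 rat strains on days 20, 30, 40 and 50 of age. DRlyp/lyp is a BB (BioBreeding) strain that becomes diabetic spontaneously and carries a mutation at the lyp locus, where Gimap5, a gene needed for T lymphocyte survival, is lost. DR+/+ is the BB strain without the mutation, in which diabetes can be induced. Flyp/lyp and F+/+ are healthy F344 strains with and without it, marked FAM and RT1u in the sample titles. Per the labels, weaning falls on day 20 and insulitis starts in DRlyp/lyp between days 40 and 50. Each strain and day was 1 RNA pool of 6 to 8 rats on 3 technical arrays, so 16 pools were the independent units (n = 4 pools per strain). Ins1, Ins2 and Gcg lay close to the highest value of the table (13.98), where differences can be compressed.

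The BB day 50 pools stood apart from all others. On the first principal component, which held 42.4% of the variance, DR+/+ and DRlyp/lyp at day 50 scored 37.2 and 30.5, DR+/+ at day 40 scored 12.5, and F344 pools lay between -15.8 and -5.42. The second component (28.3%) followed age and background. On it DRlyp/lyp went from 19.7 at day 20 to -6.46 at day 50 and Flyp/lyp from 5.13 to -17.8.

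**Figure D1:**
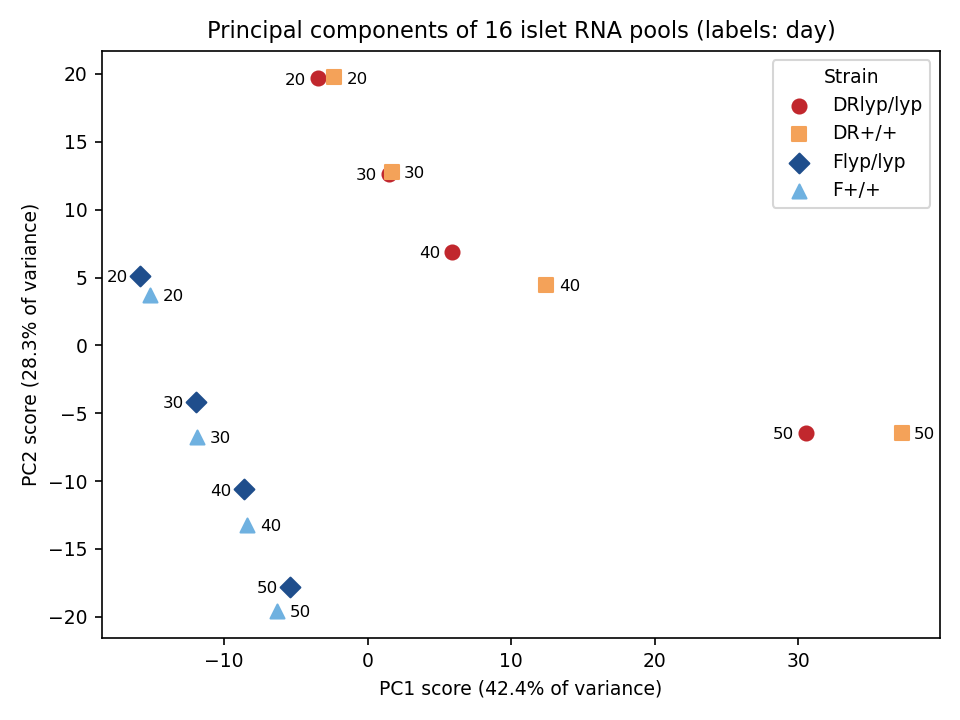
Principal components of the 16 pool means over 10927 genes. The first component held 42.4% and the second 28.3% of the variance, and the BB day 50 pools scored 30.5 and 37.2 on the first.

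Markers of α, δ and PP cells, acinar enzymes and genes of immature β cells were lower in old pools (days 40 and 50) than in young pools (days 20 and 30), while antigen presentation, macrophage and chemokine genes were higher (n = 8 pools each). Irx1 and Irx2, transcription factors of α cells, fell by 0.90 (SE 0.065) and 0.80 (SE 0.041), or 1.86-fold and 1.74-fold, and Fev fell by 0.56. Of 15 α, δ and PP cell markers 11 fell and 1 rose, also 11 and 1 adjusted over the list alone (camera adjusted p = 2.83e-06, and adjusted p = 0.403 with an estimated correlation). Gcg fell by only 0.10 (SE 0.023, and adjusted p = 0.00467), and Sst (-0.08, adjusted p = 0.149), Ins1 (0.02, adjusted p = 0.268) and Ins2 (0.04, adjusted p = 0.132) did not pass. Leaving out the Flyp/lyp day 20 pool brought Sst to adjusted p = 0.0447. Nnat, a gene that is high in immature β cells, fell by 0.82. Sox4 and Cxcl12 of the same list fell by 0.54 and 0.70 with 1 probe set each, while another Sox4 probe set gave 0.12 (adjusted p = 0.0779) and 2 others of Cxcl12 gave 0.02 (adjusted p = 0.897) and -0.24 (adjusted p = 0.0881). The list had 8 of 19 members lower and 2 higher, also 8 and 2 adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.564 with an estimated correlation), and did not pass without the F+/+ day 50 pool (adjusted p = 0.0556). Of 28 acinar enzymes 19 fell, 22 adjusted over the list alone (camera adjusted p = 9.11e-06, and adjusted p = 0.564 with an estimated correlation), with Pnliprp2 2.05-fold and Prss2 2.01-fold lower. The matrix genes Loxl1 and Col5a2 fell by 0.62 and 0.42, and 14 of 30 fibroblast genes fell while 5 rose, 15 and 5 adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.564 with an estimated correlation). Rpl14 fell by 0.16, and 12 of 44 ribosomal protein genes fell, 0 adjusted over the list alone (camera adjusted p = 0.00532, and adjusted p = 0.647 with an estimated correlation).

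Genes of immune cells rose from young to old pools, most in the BB day 50 pools. Cd74, the MHC class II invariant chain, rose by 1.39 (SE 0.36), 2.63-fold, and 8 of 9 class II genes rose, 9 adjusted over the list alone (camera adjusted p = 0.00532, and adjusted p = 0.564 with an estimated correlation). Tyrobp, a myeloid signalling adaptor, rose by 0.76 (SE 0.19), and 15 of 22 macrophage and dendritic cell markers rose, 16 adjusted over the list alone (camera adjusted p = 0.000433, and adjusted p = 0.564 with an estimated correlation). Cxcl16 and Ccl4 rose by 0.49 and 0.45, with 13 of 21 chemokines higher and 2 lower, 15 and 2 adjusted over the list alone (camera adjusted p = 0.00322, and adjusted p = 0.564 with an estimated correlation). Ifit2, an interferon-stimulated gene, rose by 0.58 (SE 0.084). Of 34 such genes 13 rose, 9 adjusted over the list alone (camera adjusted p = 0.00322, and adjusted p = 0.647 with an estimated correlation). Of 25 inflammatory and NF-kB genes 9 rose and 1 fell, also 9 and 1 adjusted over the list alone (camera adjusted p = 0.00692, and adjusted p = 0.564 with an estimated correlation). MHC class I genes (6 of 16 higher, also 6 adjusted over the list alone; camera adjusted p = 0.0094) and T cell markers (7 of 14 higher and 1 lower, 11 and 1 adjusted over the list alone; camera adjusted p = 0.0288) had adjusted p = 0.647 with an estimated correlation. Without both BB day 50 pools, left out after the data were seen, these lists had adjusted p of 0.142 and 0.0899. T cell markers also did not pass without the DR+/+ day 30 pool (adjusted p = 0.0579). B cell markers did not pass in camera (adjusted p = 0.0852), although 6 of 9 rose.

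Of 10927 genes 2361 rose and 2528 fell from young to old pools at adjusted p under 0.05 in limma, 45 and 10 of them at least 2-fold. Tmem35a, a chaperone of nicotinic receptors, rose by 1.79 (SE 0.20), 3.46-fold. Of genes of white blood cells, Plac8 rose 3.33-fold, Coro1a by 1.74 (at least 2.57-fold with the filter value as floor) and Ptprc (CD45) by 1.78 (at least 1.81-fold). Ms4a1, the B cell antigen CD20, rose by 1.88 (at least 1.26-fold, adjusted p = 0.0262), but reached adjusted p = 0.0598 without the DR+/+ day 30 pool and was also lost without DR+/+ day 20, Flyp/lyp day 40 or DRlyp/lyp day 50. The largest falls were Reg1a (3.36-fold), Gjb6, a connexin (1.49, SE 0.14, at least 2.06-fold), Tff2 (2.56-fold), the growth factor binding protein Igfbp2 (1.35, SE 0.09, 2.54-fold), the globin gene Hbb (2.16-fold) and the taste G protein gene Gnat3 (2.11-fold). Leaving out both BB day 50 pools gave 5094 genes. Other lists did not pass in camera, among them β cell markers (10 of 24 higher, 7 lower, and adjusted p = 0.238), proliferation genes (2 of 40 higher, and adjusted p = 0.681), ductal markers (adjusted p = 0.283), GIMAP genes (0 of 5, and adjusted p = 0.36) and Schwann and neural markers (adjusted p = 0.0577).

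BB islets had more stromal, ductal and ghrelin or PP cell transcripts than F344 islets and less of several secretory and acinar transcripts (n = 8 pools each). Krt19, a duct keratin, was higher in BB by 3.17 (SE 0.12), 8.99-fold, and Ghrl and Ppy were 2.79-fold and 1.71-fold higher, while Sst was 1.53-fold lower (-0.61, SE 0.043). Of 12 ductal markers 7 were higher and 1 lower, also 7 and 1 adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.331 with an estimated correlation). Their pool medians lay between 0.026 and 0.229 in BB and between -0.235 and -0.002 in F344, so the list moved less than Krt19. The matrix genes Dpt (1.07, SE 0.041, 2.1-fold) and Col6a3 (0.95, 1.93-fold) were higher, with 20 of 30 fibroblast genes higher and 3 lower, 20 and 4 adjusted over the list alone (camera adjusted p = 2.75e-05, and adjusted p = 0.634 with an estimated correlation). Cela3b, a pancreatic elastase, was lower by 0.55, with 8 of 28 acinar enzymes lower, 7 adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.755 with an estimated correlation). Edem2, Dnajb11 and Manf of the unfolded protein response were lower by 0.37, 0.30 and 0.28. In that list 16 of 30 genes were lower and 2 higher, 17 and 2 adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.603 with an estimated correlation). Nr4a2 and Ier2 of the immediate early and isolation stress list, which tissue handling also induces, were higher by 0.34 each, with 18 of 29 such genes higher and 2 lower, also 18 and 2 adjusted over the list alone (camera adjusted p = 0.00443, and adjusted p = 0.755 with an estimated correlation). Ins1 (0.00), Ins2 (0.01) and Gcg (0.03) did not differ at adjusted p of 0.926, 0.725 and 0.337.

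Some BB differences touched immune genes. Gimap5 was higher in BB by 0.60 (SE 0.13), 1.51-fold (adjusted p = 0.003), and 4 of 5 GIMAP genes were higher, 5 adjusted over the list alone (camera adjusted p = 0.035, and adjusted p = 0.755 with an estimated correlation). Gimap4 reached adjusted p = 0.0501 without the Flyp/lyp day 50 pool. Cfd and C1r of complement were higher by 0.89 and 0.70, with 5 of 9 genes higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.755 with an estimated correlation). The Cfd means lay below the expression filter in both backgrounds (4.475 in BB and 3.583 in F344). Macrophage markers (5 of 22 higher, 1 adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.755 with an estimated correlation) included Cd14, 1.59-fold higher, but the list had adjusted p = 0.0768 without the DRlyp/lyp day 50 pool and 0.0542 without F+/+ day 50. The α, δ and PP cell list (9 of 15 higher, 3 lower, 10 and 3 adjusted over the list alone; camera adjusted p = 0.0433, and adjusted p = 0.755 with an estimated correlation) was lost without any 1 of 6 pools, at most at adjusted p = 0.0757 without DR+/+ day 40. Ccl11, a chemokine named in the labels, had strain means of 3.58 (SD 0.18) in DRlyp/lyp, 3.48 (SD 0.42) in DR+/+, 2.68 (SD 0.12) in Flyp/lyp and 2.64 (SD 0.068) in F+/+ (n = 4 pools each). It was higher in BB by 0.87 (SE 0.089, adjusted p = 1.15e-05) and did not differ between DRlyp/lyp and DR+/+ (0.10, adjusted p = 0.952). Its levels lay below the expression filter.

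Of 10927 genes 2362 were higher and 2440 lower in BB than in F344 in limma, 56 and 32 of them at least 2-fold. Fam111a, a protease gene, was higher by 6.78 (SE 0.12), at least 74.2-fold with the filter value as floor, Pxmp4 8.96-fold, Cyp4v3 7.94-fold, Pdgfrl 4.79-fold and Bmp3 at least 1.92-fold (2.33). Klkb1, plasma kallikrein, was at least 3.09-fold lower (-3.19, SE 0.086), and Cuzd1, a zymogen granule gene, 5.62-fold lower. Ptgs1 and Nqo2 were 3.71-fold and 3.69-fold lower, while another Ptgs1 probe set gave -0.365 (adjusted p = 2.03e-05). A probe set that binds a strain variant differently could give part of such differences, which was not tested. Slc17a4 was 3.33-fold lower, and Ptprn2, a secretory granule gene and islet autoantigen, 3.28-fold lower (-1.71, SE 0.03). Ribosomal protein genes were slightly higher, with 27 of 44 higher and 2 lower, 31 and 2 adjusted over the list alone (median 0.11; camera adjusted p = 0.000179, and adjusted p = 0.755 with an estimated correlation). Leaving out both BB day 50 pools gave 4191 genes.

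T cell markers, immediate early and isolation stress genes, and proliferation genes were lower as lists in DRlyp/lyp than in DR+/+ over the 4 days together, and no single gene passed (n = 4 pools each). Gimap5 was lower in DRlyp/lyp on 4 of 4 days, by 0.87 on average (SE 0.18), 1.82-fold, at adjusted p = 0.609. In limma 0 genes passed and 556 had unadjusted p under 0.05. 1 gene passed without the DR+/+ day 20 pool, 1 with every probe set tested, 19 (5 higher and 14 lower) with the pool as a random effect, and 106 with all arrays taken as independent, which counts technical arrays as rats. T cell markers were lower as a list (median -0.38, Zap70 -0.42; camera adjusted p = 2.2e-09, and adjusted p = 0.404 with an estimated correlation), with 0 of 14 members passing. Immediate early and isolation stress genes were also lower (median -0.19, Ier2 -0.35; 0 of 29 over all genes, 1 adjusted over the list alone; camera adjusted p = 1.15e-12, and adjusted p = 0.404 with an estimated correlation). So were proliferation genes (Tk1 -0.27; 1 of 40 adjusted over the list alone; camera adjusted p = 3.04e-12, and adjusted p = 0.443 with an estimated correlation). These 3 lists passed when any single pool was left out, but not every day had the same sign. The mean level of immediate early and isolation stress genes was 0.08 in DRlyp/lyp and -0.09 in DR+/+ at day 30, 0.01 and 0.52 at day 40, and 0.07 and 0.32 at day 50. That of proliferation genes was -0.20 and -0.21 at day 40 and 0.02 and 0.40 at day 50. The mean level of T cell markers was lower in DRlyp/lyp on each day, with 0.57 and 1.39 at day 50.

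Several other list shifts of the mutation in BB were lost when certain single pools were left out. The mean level of B cell markers was nevertheless lower in DRlyp/lyp than in DR+/+ on each day, with -0.476 and 0.203 at day 40 and 1.791 and 2.925 at day 50. Interferon-stimulated genes were higher (median 0.20; 0 of 34 passing; camera adjusted p = 1.61e-06, and adjusted p = 0.531 with an estimated correlation), but turned to the other direction without the DRlyp/lyp day 50 pool (adjusted p = 0.71). B cell markers were lower (median -0.46; camera adjusted p = 0.0031, and adjusted p = 0.531 with an estimated correlation), with adjusted p = 0.965 in the other direction without DR+/+ day 50 and 0.0809 without DRlyp/lyp day 40. GIMAP genes were lower (median -0.24; 1 of 5 adjusted over the list alone; camera adjusted p = 0.00252, and adjusted p = 0.443 with an estimated correlation), with adjusted p = 0.807 without DR+/+ day 50. Acinar enzymes were lower (median -0.23; camera adjusted p = 3.1e-06, and adjusted p = 0.531 with an estimated correlation), with adjusted p = 0.0787 without DRlyp/lyp day 50. T cell (adjusted p = 2.67e-12) and B cell markers (adjusted p = 4.26e-05) still passed without both BB day 50 pools, and interferon-stimulated genes (0.851), acinar enzymes (0.456) and GIMAP genes (0.118) did not.

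On single days the BB strains differed most at day 50, where each group was 1 pool on 3 arrays. Cxcl9, an interferon-induced chemokine, was higher in DRlyp/lyp by 4.26 (SE 0.15), at least 8.35-fold since DR+/+ lay below the expression filter, Ubd 9.05-fold and Ifgga2l1 7.85-fold. Glycam1, a ligand of lymphocyte homing receptors in lymph node vessels, was 6.67-fold lower, Reg3b 4.75-fold and the T cell factor Tcf7 4.28-fold, and Gimap5 was 2.79-fold lower (-1.48). At day 40 Prss3bl1, a trypsin-like gene, was 5.39-fold higher, and Dmbt1, Cxcl1 and Atf3 were 5.27-fold, 4.93-fold and 3.8-fold lower. In the same DR+/+ day 40 pool the immediate early and isolation stress list stood at 0.52, against 0.01 in DRlyp/lyp. Prss3bl1 was also 7.07-fold higher at day 30 and 2.36-fold at day 20, and Reg3a, a regenerating gene, was 3.07-fold higher at day 20. In limma with a 2-fold threshold 3 genes were higher and 2 lower at day 20, 5 and 0 at day 30, 3 and 27 at day 40, and 28 and 83 at day 50. These p values measure array spread and hold for the pools compared. On simulated data the day 50 comparison in BB gave 59 false calls. The simulated pool spread included the departing BB day 50 pools, so this number does not gauge the counts at days 20, 30 and 40.

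A small set of genes separated Flyp/lyp from F+/+ (n = 4 pools each). Retsat, a retinol saturase, was higher in Flyp/lyp by 1.22 (SE 0.036), 2.34-fold, and LOC100910237 by 3.11 (SE 0.057), at least 3.03-fold since F+/+ lay below the expression filter. Osbpl3, a lipid-binding protein gene, was 2.52-fold higher (1.33, SE 0.067) with 1 probe set, while another gave -0.22 (adjusted p = 0.491). Tmsb10-ps5 and Ptcd3 were 1.77-fold and 1.74-fold higher. Dennd2a and Moxd1 were lower by 0.64 (SE 0.055) and 0.62 (SE 0.061), and Aplf by 0.59. Ppp1r17 was lower by 1.29 (at least 1.39-fold, adjusted p = 0.0441) but was lost without any 1 of 12 pools, at most at adjusted p = 0.162. Fut1 and Mgmt were lost without any 1 of 6 pools, at most at adjusted p of 0.107 and 0.106. Gimap5 was lower on 4 of 4 days, by 0.79 (SE 0.18), 1.73-fold, at adjusted p = 0.152, and at adjusted p = 0.00204 without the DR+/+ day 50 pool. In limma 14 genes were higher and 24 lower, 3 and 1 of them at least 2-fold. The 4 regenerating genes had a median of 2.82, with 0 passing over all genes and 3 adjusted over the list alone.

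Apart from the regenerating genes, lists had medians between -0.26 and 0.11 for the mutation in F344, and 0 list members passed over all genes. Col6a3 and Dpt were lower by 0.39 and 0.29 (adjusted p of 0.158 and 0.0673), and 30 fibroblast genes were lower as a list (median -0.15; 3 adjusted over the list alone; camera adjusted p = 3.74e-11, and adjusted p = 0.19 with an estimated correlation). Eng, an endothelial receptor, was lower by 0.22, and 8 of 18 endothelial markers were lower adjusted over the list alone (median -0.11; camera adjusted p = 1.21e-07, and adjusted p = 0.126 with an estimated correlation). Acinar enzymes were lower (camera adjusted p = 4.76e-06, and adjusted p = 0.928 with an estimated correlation), with adjusted p = 0.053 without Flyp/lyp day 30. Oxidative phosphorylation genes were higher (camera adjusted p = 1.84e-05, and adjusted p = 0.928 with an estimated correlation). The unfolded protein response list, with Pdia4 lower by 0.17, was lower (1 of 30 adjusted over the list alone; camera adjusted p = 0.000194, and adjusted p = 0.19 with an estimated correlation).

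On single days Reg3a and Reg3b, secreted regenerating lectins, and LOC100910237 were higher in Flyp/lyp. LOC100910237 was higher by 3.06, 3.09, 3.06 and 3.23 on the 4 days, at least 2.81-fold at day 20 and 3.15-fold at day 30. Reg3a was higher in Flyp/lyp at day 50 by 6.47 (SE 0.089), at least 34.4-fold, 32.4-fold at day 40, 6.24-fold at day 30 and at least 9.81-fold at day 20. Reg3b was higher at least 31.9-fold at day 50, and 28.2-fold, 6.37-fold and 7.24-fold at days 40, 30 and 20. The bounds take the filter value as floor, below which F+/+ lay, so the days are not ranked. In Flyp/lyp Reg3a had values of 8.05, 9.28, 9.82 and 9.86 over the 4 days, and in F+/+ 3.97, 6.64, 4.8 and 3.39. Vip, a neuropeptide, was at least 1.57-fold lower in Flyp/lyp at day 50 (-2.01). Tff2 was 2.88-fold lower at day 30. At day 40 Gadl1 and Stk32c were lower by 1.69 and 1.42. The number of false calls among the counts that follow is not known. The 59 false calls of the simulated day 50 comparison in BB do not gauge it, since that pool spread included the departing BB day 50 pools. In limma with a 2-fold threshold 12 genes were higher and 1 lower at day 20, 12 and 10 at day 30, 11 and 3 at day 40, and 7 and 14 at day 50, with p from array spread and 1 pool per group.

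The effect of the mutation differed between backgrounds for 14 genes, whose lyp effects in BB lay between -0.02 and 0.09. Of these 14 genes 9 (64.3%) lay on the chromosome of Gimap5, against 5.62% of the other genes, a count made after the result was seen. LOC100910237, Osbpl3 and Retsat were higher with the mutation in F344 and had values of -0.00, 0.09 and 0.05 in BB, a difference of -3.11 (SE 0.081), -1.24 (SE 0.094) and -1.18 (SE 0.052). The other Osbpl3 probe set gave 0.44 (adjusted p = 0.5). Moxd1 and Dennd2a were lower with it in F344, a difference of 0.70 and 0.72. In limma 8 genes were higher and 6 lower in this difference, and 590 had unadjusted p under 0.05. Without the Flyp/lyp day 20 pool 5 genes passed. Immediate early and isolation stress genes (0 of 29 over all genes, 4 adjusted over the list alone; camera adjusted p = 2.14e-12, and adjusted p = 0.679 with an estimated correlation) and T cell markers (0 of 14; camera adjusted p = 0.000713, and adjusted p = 0.7 with an estimated correlation) had a lower lyp effect in BB. The T cell list had adjusted p = 0.257 without DR+/+ day 50 and 0.0702 without F+/+ day 50. Endothelial markers had a higher one (1 of 18 adjusted over the list alone; camera adjusted p = 0.000632, and adjusted p = 0.679 with an estimated correlation).

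Interferon-stimulated genes set the DRlyp/lyp day 50 pool apart from what its strain and day alone gave. Cxcl9, Cxcl10 and Cxcl11, chemokines that draw T cells, were above this by 4.69 (SE 0.18), 3.11 (SE 0.39) and 2.76 (SE 0.12), or at least 8.35-fold, 8.64-fold and 6.77-fold. The guanylate binding protein Gbp2 was higher at least 7.53-fold, Igtp 6.06-fold and Isg15 5.21-fold. Bounds take the filter value as floor. Ubd, an inflammatory ubiquitin-like modifier, was above the fitted value by 5.41 (SE 0.87, adjusted p = 0.0171), with no fold given since 3 of the strain's 4 pools lay below the filter, and had adjusted p = 0.0668 without DRlyp/lyp day 20, 0.0527 without day 30 and 0.0576 without day 40 of that strain. Ifgga2l1 was at least 8.22-fold higher, and Gbp7 higher by 3.45 (adjusted p = 0.0279), although Gbp7 was lost without any 1 of 9 pools, at most at adjusted p = 0.0967. Of 34 interferon-stimulated genes 19 were higher, 26 adjusted over the list alone (median 0.83; camera adjusted p = 3.91e-61, and adjusted p = 0.0011 with an estimated correlation).

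Antigen processing, complement, chemokine and macrophage genes were also higher in that pool, but they rose in the DR+/+ day 50 pool too. In the fit below with a coefficient for each BB day 50 pool, median rises were compared between DRlyp/lyp and DR+/+. They were 0.60 and 0.37 for class I genes, 0.92 and 0.59 for complement, 0.61 and 0.48 for chemokines and 1.256 and 1.065 for macrophage markers. Interferon-stimulated genes had 0.84 and 0.12. Tap1, the peptide transporter, was 4.25-fold higher (2.09, SE 0.14), with 2 of 16 MHC class I genes higher, 14 adjusted over the list alone (camera adjusted p = 1.65e-23, and adjusted p = 0.039 with an estimated correlation). RT1-S3 (adjusted p = 0.0396) was lost without any 1 of 13 pools, at most at adjusted p = 0.134. Of 21 chemokines 5 were higher, 8 adjusted over the list alone (camera adjusted p = 1.6e-14, and adjusted p = 0.039 with an estimated correlation). Serping1, the C1 inhibitor, was 2.22-fold higher, with 1 of 9 complement genes higher, 5 adjusted over the list alone (camera adjusted p = 5.63e-09, and adjusted p = 0.039 with an estimated correlation). Fcgr3a was 2.51-fold and Itgax at least 1.54-fold higher, with 3 of 22 macrophage markers higher, 11 adjusted over the list alone (camera adjusted p = 2.65e-19, and adjusted p = 0.0678 with an estimated correlation). Acinar enzymes were lower (median -0.57; 0 of 28; camera adjusted p = 1.09e-09, and adjusted p = 0.492 with an estimated correlation), and class II genes higher (median 1.28; 0 of 9; camera adjusted p = 0.000221, and adjusted p = 0.492 with an estimated correlation). B cell markers were higher (median 0.90; 0 of 9; camera adjusted p = 0.0121, and adjusted p = 0.699 with an estimated correlation), with adjusted p = 0.261 without F+/+ day 50, 0.181 without Flyp/lyp day 50 and 0.0591 without DRlyp/lyp day 40. T cell markers did not pass (adjusted p = 0.194).

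In limma 55 genes were above and 2 (Snx7 and Aph1bl2) below the value from strain and day in the DRlyp/lyp day 50 pool, 27 and 0 at least 2-fold. Aph1bl2 was lost without any 1 of 4 pools, at most at adjusted p = 0.0677. Ins1 (0.01), Ins2 (-0.00) and Gcg (0.03) were unchanged within their SE of 0.048, 0.05 and 0.063. Without the DR+/+ day 50 pool 408 genes passed, and without DRlyp/lyp day 30 only 41. The DR+/+ day 50 pool tested in the same way had 90 genes above and 2 below, Flyp/lyp day 30 had 7, and the other pools 0. With both BB day 50 pools given their own coefficients, a choice made after the data were seen, 8 of 9 class II genes and 8 of 9 B cell markers rose in DRlyp/lyp, and 8 and 9 in DR+/+. Of 34 interferon-stimulated genes 24 rose in DRlyp/lyp and 3 in DR+/+. These are 1 pool per strain, so their spread came from the other pools and not from replicates of either. In this fit the rise differed between these pools for 18 interferon-stimulated genes, all higher in DRlyp/lyp, and for 3 of 5 GIMAP genes and 3 of 9 B cell markers, all lower.

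**Figure D2:**
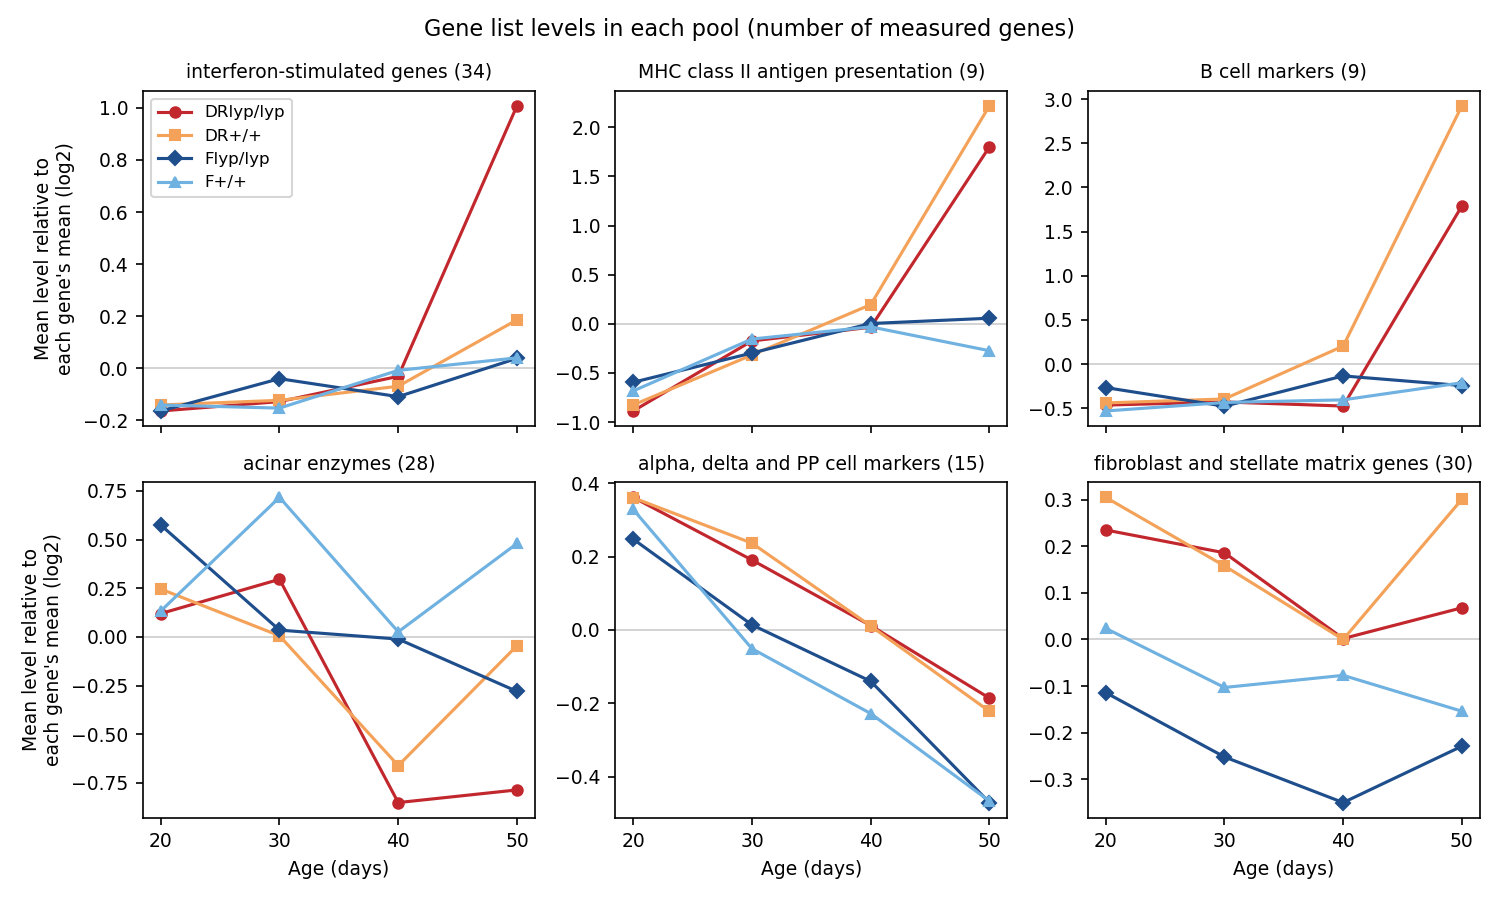
Mean level of 6 gene lists in each pool relative to each gene's mean over 16 pools. At day 50 interferon-stimulated genes reached 1.01 in DRlyp/lyp and 0.19 in DR+/+, and B cell markers 1.79 and 2.92.

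With age, interferon and class II genes rose in DRlyp/lyp and regenerating genes fell (slope per 10 days, n = 4 pools). Cxcl10 rose 2.4-fold, Cd74 by 1.17 (SE 0.18), 2.25-fold, Ubd by 2.18 (SE 0.47), Cxcl9 by 1.51 and Slpi, a protease inhibitor, by 1.48. Ubd and Cxcl9 lay below the expression filter in 3 of 4 pools and Slpi in 1, so their slopes carry no fold. Reg3a, below it in 1 pool, fell by 1.99 (SE 0.44), Reg3b 3.81-fold, Reg1a 2.69-fold and Irx2 1.3-fold (0.37, SE 0.037). Of 34 interferon-stimulated genes 21 rose, 26 adjusted over the list alone (camera adjusted p = 1.51e-13), of 16 class I genes 12, 15 adjusted over the list alone (camera adjusted p = 2.22e-10), of 9 class II genes 7, 8 adjusted over the list alone (camera adjusted p = 2.05e-07), and of 22 macrophage markers 14, 19 adjusted over the list alone (camera adjusted p = 1.15e-11). Of 15 α, δ and PP cell markers 8 fell, 9 adjusted over the list alone (camera adjusted p = 3.18e-08). Each of these 5 lists had adjusted p = 0.29 with an estimated correlation. Acinar enzymes fell (4 of 28, 19 adjusted over the list alone; camera adjusted p = 1.23e-09, and adjusted p = 0.353 with an estimated correlation). Much of this was lost without the day 20 or day 50 pool, the ends of the slope, whose removal weakens any slope by construction. The rise of interferon-stimulated genes was not gradual, with mean levels of -0.16, -0.13, -0.03 and 1.01 in DRlyp/lyp over the 4 days. Class II genes had -0.89, -0.17, -0.035 and 1.80. The α, δ and PP cell markers fell from each day to the next (0.36, 0.19, 0.01 and -0.19). Without the DRlyp/lyp day 50 pool Ubd had adjusted p = 0.507, Cxcl9 0.564, Cxcl10 0.34, Slpi 0.266, Cd74 0.173 and the interferon list 0.259. Without its day 20 pool Reg3a had adjusted p = 0.35, Reg3b 0.323, Reg1a 0.133, Cd74 0.0719 and Slpi 0.0649, and the Reg genes were also lost without day 50. In limma 503 genes rose and 561 fell, and 44 passed without the day 50 pool.

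In DR+/+ lymphocyte genes rose with age (n = 4 pools). Cd74 rose 2.43-fold per 10 days, Cxcl13, a B cell attracting chemokine, by 2.33 (SE 0.64), Ms4a1 by 2.03 (SE 0.46), the activation marker Cd69 by 1.90, Ptprc by 1.78 and Cd3d of the T cell receptor complex by 0.78 (SE 0.12). Cxcl13 and Cd3d lay below the expression filter in 3 of 4 pools, and Ms4a1, Cd69 and Ptprc in 2, so their slopes carry no fold. Irx1 fell by 0.47 (SE 0.043), 1.39-fold, and 1810009J06Rikl 2.24-fold. Of 9 class II genes 9 rose, also 9 adjusted over the list alone (camera adjusted p = 1.91e-08, and adjusted p = 0.401 with an estimated correlation), of 14 T cell markers 11, 12 adjusted over the list alone (camera adjusted p = 2.51e-07), and of 9 B cell markers 8, also 8 adjusted over the list alone (camera adjusted p = 4.06e-05). Of 5 GIMAP genes 2 rose, 4 adjusted over the list alone (camera adjusted p = 0.00271). T cell, B cell and GIMAP lists had adjusted p = 0.41 with an estimated correlation. Only 3 of 34 interferon-stimulated genes rose (camera adjusted p = 0.0157, and adjusted p = 0.699 with an estimated correlation). Gimap5 rose by 0.33 (adjusted p = 0.0437), lost without any 1 of 12 pools, with adjusted p = 0.991 without DR+/+ day 50. Without the day 50 pool Cxcl13 had adjusted p = 0.694, Ms4a1 0.415, Cd69 0.222, Ptprc 0.177, Cd74 0.0983 and Cd3d 0.142, and the B cell list had 0.272, GIMAP genes 0.764 and interferon-stimulated genes 0.47. Cxcl13 was also lost without DR+/+ day 30 (adjusted p = 0.0547), and 1810009J06Rikl without DR+/+ day 20 (adjusted p = 0.147). In limma 890 genes rose and 1029 fell, and 261 passed without DR+/+ day 50.

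**Figure D3:**
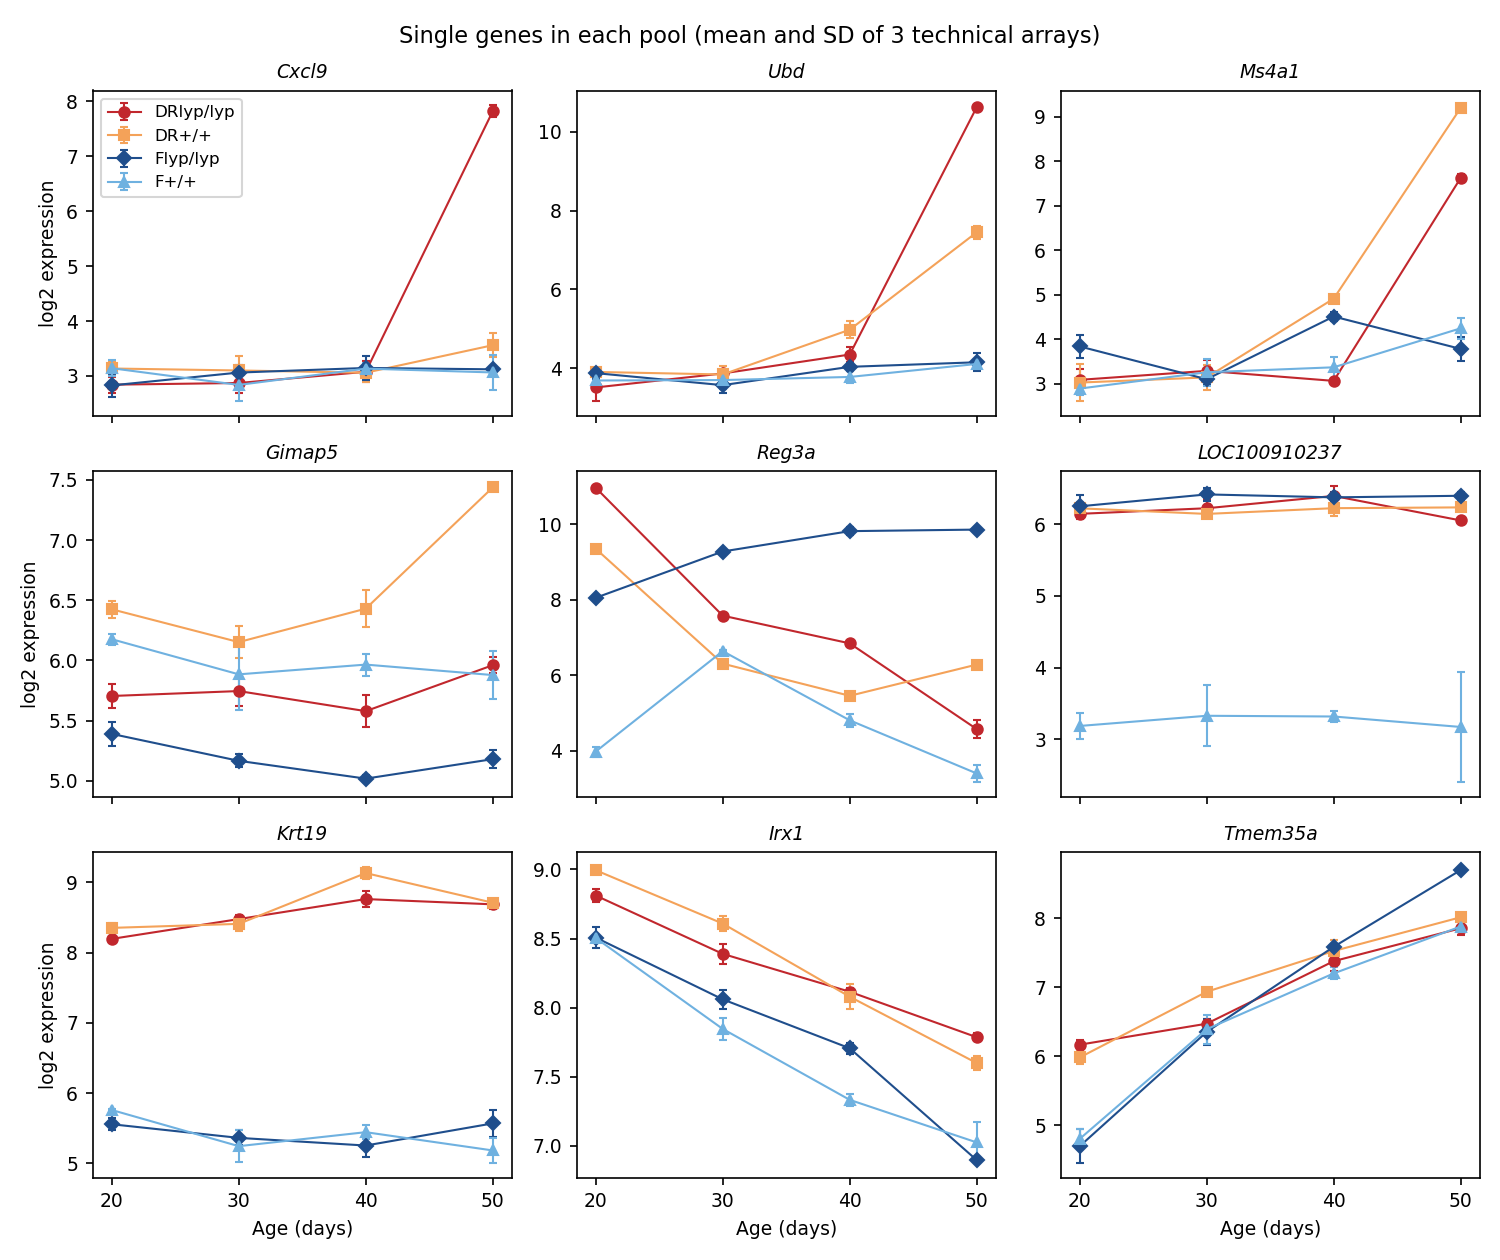
Pool means of 9 genes by age with the SD of 3 technical arrays. Reg3a reached 9.86 in Flyp/lyp and 3.39 in F+/+ at day 50, and Cxcl9 7.82 in DRlyp/lyp and 3.56 in DR+/+.

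In the F344 strains aging changed endocrine and ribosomal genes (n = 4 pools each). Tmem35a rose by 1.32 (SE 0.09) per 10 days in Flyp/lyp, where 1 pool lay below the expression filter, and 2-fold in F+/+, and Tpd52l1 1.98-fold and 1.75-fold. The granzyme inhibitor Serpinb9b rose by 0.72 and 0.92, with 2 and 1 pools below the filter. Astn1 rose 1.59-fold and 1.66-fold, and Ntm 1.5-fold in Flyp/lyp. Irx1 fell by 0.52 and 0.50. Of 15 α, δ and PP cell markers 10 fell in Flyp/lyp, 11 adjusted over the list alone (camera adjusted p = 3.03e-06, and adjusted p = 0.581 with an estimated correlation), and 11 in F+/+, 12 adjusted over the list alone (camera adjusted p = 2.46e-09, and adjusted p = 0.216 with an estimated correlation). Of 44 ribosomal protein genes 23 fell in Flyp/lyp, 31 adjusted over the list alone (camera adjusted p = 1.23e-08, and adjusted p = 0.7 with an estimated correlation), and 22 in F+/+, 34 adjusted over the list alone (camera adjusted p = 2.24e-11, and adjusted p = 0.761 with an estimated correlation). Gjb6 and Igfbp2 fell by 0.85 and 0.77 in Flyp/lyp and by 0.90 and 0.76 in F+/+. Gjb6 had adjusted p = 0.145 without Flyp/lyp day 50 and, in F+/+, 0.147 without day 20 and 0.105 without day 50. Igfbp2 had adjusted p = 0.0578 without Flyp/lyp day 20 and 0.0902 without F+/+ day 20. The retinol carrier Rbp4 fell 1.39-fold in F+/+, and Igf2bp2 1.47-fold with 1 probe set, while another gave -0.00 (adjusted p = 0.976). In limma 906 genes rose and 1421 fell in Flyp/lyp, and 936 and 1041 in F+/+. These counts were 211 without Flyp/lyp day 50 and 137 without F+/+ day 20.

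The DRlyp/lyp slope differed from the mean of the other 3 strains for 0 genes in limma, with 657 at unadjusted p under 0.05. With the pool as a random effect 122 genes passed, with all arrays taken as independent 414, and 15 without the DRlyp/lyp day 40 pool. Interferon-stimulated genes had a steeper rise as a list (0 of 34 over all genes, 17 adjusted over the list alone; camera adjusted p = 4.36e-19, and adjusted p = 0.415 with an estimated correlation). So had class I genes (0 of 16, 10 adjusted over the list alone; camera adjusted p = 1.5e-12, and adjusted p = 0.415 with an estimated correlation) and macrophage markers (0 of 22, 6 adjusted over the list alone; camera adjusted p = 1.91e-09, and adjusted p = 0.415 with an estimated correlation). Without the DRlyp/lyp day 50 pool none of the 3 had a steeper rise, since interferon-stimulated genes (adjusted p = 0.152) and macrophage markers (0.0837) turned to the other direction and class I genes had adjusted p = 0.987.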

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

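The tests of explanations below were chosen after the result was seen, and the count over other assignments was planned before the data were examined.

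The lyp effect in BB minus that in F344 differed from 0 for 14 genes on 16 pools. It was negative for LOC100910237 (-3.11), Osbpl3 (-1.24), Retsat (-1.18), Tmsb10-ps5 (-0.84), Ppm1k (-0.44) and Zfp212 (-0.37). It was positive for Atp6v1c1 (0.35), Sgk1 (0.38), Thnsl2 (0.43), Scrn1 (0.48), Bpgm (0.50), Fat1 (0.52), Moxd1 (0.70) and Dennd2a (0.72). Osbpl3 binds oxysterols, Retsat saturates retinol, Ppm1k acts in branched-chain amino acid breakdown and Sgk1 is a stress-induced kinase. With strain labels exchanged, 5 of 100 assignments gave at least as many genes, the real one 14 and the highest other 24, so chance was not excluded for the count. LOC100910237, Osbpl3, Retsat, Moxd1 and Dennd2a passed without any single pool. Bpgm, Zfp212, Scrn1, Thnsl2, Ppm1k, Tmsb10-ps5, Fat1, Sgk1 and Atp6v1c1 were lost without at least 1 pool, all 9 of them without Flyp/lyp day 20. All 14 were also among the 38 genes separating Flyp/lyp from F+/+. Of the 14, 9 (64.3%) lay on the chromosome of Gimap5, against 613 of 10906 other genes (5.62%; Fisher's exact two-sided p = 9.23e-09). This overlaps the result for those 38 genes below and is not separate from it.

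Genes separating Flyp/lyp from F+/+ lay on the chromosome of Gimap5 more often than other genes, 16 of 38 (42.1%) against 606 of 10882 (5.57%; Fisher's exact two-sided p = 6.98e-11). A BB chromosome segment carried with the lyp allele into F344 may account for part of them. Retsat was at the BB level, with means of 8.4 in Flyp/lyp, 8.44 in DRlyp/lyp and 7.18 in F+/+. Tmsb10-ps5 (6.10, 5.32 and 5.28) and Dennd2a (6.30, 6.99 and 6.94) were not at the BB level, which alone does not exclude such a segment. LOC100910237 lies on another chromosome and was also at the BB level (6.36, 6.20 and 3.25), which BB segments elsewhere could give. Of the 16 genes 11 (68.8%) were nearer to BB in Flyp/lyp than in F+/+ (exact binomial two-sided p = 0.21), and of the 22 elsewhere 8 (exact binomial two-sided p = 0.286), which left this open. A probe set that binds a strain variant differently could give such differences. Of 7 other probe sets 6 (85.7%) went the same way with 2 passing and Osbpl3 the exception (-0.22), too few to decide. In BB 0 genes passed for the mutation, and the 14 genes above had lyp effects between -0.02 and 0.09. The 14 were picked for differing between backgrounds, so their small effects in BB follow in part from that choice. No conclusion on an action of Gimap5 loss in BB is drawn from them. An action of Gimap5 loss limited to F344 was not tested.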

How the results depend on the processing

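Leaving out both BB day 50 pools, and giving the DR+/+ day 50 pool its own coefficient, were chosen after the data were seen. All other alternatives were planned before the data were examined.

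With every probe set tested instead of 1 per gene, 8716 probe sets passed for old against young, 8174 for BB against F344, 1 for lyp in BB and 66 for lyp in F344. Slopes passed for 1696 in DRlyp/lyp, 3186 in DR+/+, 4057 in Flyp/lyp and 3654 in F+/+. On single days 11 passed in BB at day 20, 8 in BB at day 30, 24 in F344 at day 20 and 28 in F344 at day 40. More was tested by construction. With the filter on the mean over all arrays fewer genes were tested, and 12 passed in BB at day 40, 43 in BB at day 50 and 9 in F344 at day 40.

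With the pool as a random effect and the replicate number as block, 19 genes passed for lyp in BB, 214 for lyp in F344, 73 for lyp by background, 134 for the day 50 departure of DRlyp/lyp, 2164 for its slope and 122 for the slope difference. Replicate numbers did not pair arrays. With all 48 arrays taken as independent, which counts technical arrays as rats by construction, 106 passed for lyp in BB, 704 for lyp in F344, 253 for lyp by background and 398 for the departure. Slopes then passed for 3760 genes in DRlyp/lyp, 4450 in DR+/+, 4859 in Flyp/lyp, 4458 in F+/+ and 414 for the difference.

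Without both BB day 50 pools the slope passed for 221 genes in DRlyp/lyp and 493 in DR+/+. With its own coefficient for the DR+/+ day 50 pool the departure rose to 408 genes. This is the same fit to the other pools as leaving that pool out, so it is not a separate check. In both, the DR+/+ day 50 pool no longer enters the day 50 term or the spread. Leaving out the day 50 pools also shortens the BB slopes, which weakens them by construction. Lymph node and acinar markers of the DR+/+ day 50 pool are given under other observations, and they did not settle what set this pool apart.

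Leaving out 1 pool or replicate number gave 0 to 1 genes for lyp in BB, 5 to 16 for lyp by background, 41 to 408 for the departure and 0 to 15 for the slope difference. Slopes ranged from 44 to 1425 genes in DRlyp/lyp, 261 to 2060 in DR+/+, 211 to 2556 in Flyp/lyp and 137 to 2139 in F+/+. Without its day 20 or day 50 pool the slope passed for 107 and 44 genes in DRlyp/lyp and 855 and 261 in DR+/+. In Flyp/lyp it passed for 277 and 211, and in F+/+ for 137 and 529. These days are the ends of the age range, so leaving out either weakens a slope by construction. Without day 30 or day 40 the DRlyp/lyp slope passed for 726 and 1063. The cause of the other changes was not tested.

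Over the same omissions, adjusted p ranged from 7.65e-05 to 0.965 for the B cell markers list in lyp in BB, from 0.0012 to 0.275 for the MHC class I antigen presentation list in lyp in BB and from 0.00116 to 0.965 for the beta cell markers list in lyp in BB. It ranged from 2.7e-05 to 0.726 for the cytosolic ribosomal proteins (pattern) list in lyp in BB and from 3.53e-11 to 0.71 for the interferon-stimulated genes list in lyp in BB. For the interferon-stimulated genes list in lyp by background it ranged from 1.54e-08 to 0.973. With an estimated correlation these lists had adjusted p of 0.531, 0.734, 0.531, 0.755, 0.531 and 0.7 in this order. Without both BB day 50 pools the β cell list moved the other way for lyp in BB (adjusted p = 0.851). Leaving out a single pool turned the direction of all 5 lists for lyp in BB and of the interferon list in lyp by background. The cause was not tested.

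Adjusted p ranged from 1.59e-05 to 0.557 for the B cell markers list in slope in DRlyp/lyp, from 9.12e-06 to 0.325 for the T cell markers list in slope in DRlyp/lyp and from 5.29e-08 to 0.736 for the complement genes list in slope in DRlyp/lyp. It ranged from 0.00952 to 0.956 for the cytosolic ribosomal proteins (pattern) list in slope in DR+/+ and from 3.57e-06 to 0.634 for the proliferation genes list in slope in DR+/+. With an estimated correlation these lists had adjusted p of 0.471, 0.486, 0.29, 0.699 and 0.699 in this order. All 5 changed direction without their own strain's day 50 pool, and also without both BB day 50 pools, with adjusted p = 0.725 for B cell, 0.273 for T cell, 0.858 for complement, 0.956 for ribosomal and 0.583 for proliferation genes. In DRlyp/lyp the mean levels over days 20, 30, 40 and 50 were -0.465, -0.430, -0.476 and 1.791 for B cell markers. They were -0.228, -0.269, -0.273 and 0.573 for T cell markers, and 0.006, 0.008, 0.047 and 0.851 for complement genes. The rise of these lists therefore lay in the day 50 pool. The cause of the changes in DR+/+ was not tested.

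For the slope of DRlyp/lyp against the others, adjusted p ranged from 5.25e-08 to 0.148 for the MHC class II antigen presentation list in slope DRlyp/lyp minus others and from 1.83e-09 to 0.0385 for the chemokine ligands list in slope DRlyp/lyp minus others. It ranged from 5.19e-08 to 0.719 for the cholesterol synthesis list in slope DRlyp/lyp minus others and from 1.91e-09 to 0.152 for the complement genes list in slope DRlyp/lyp minus others. It ranged from 7.63e-38 to 0.152 for the interferon-stimulated genes list in slope DRlyp/lyp minus others and from 1.75e-17 to 0.0837 for the macrophage and dendritic cell markers list in slope DRlyp/lyp minus others. With an estimated correlation these lists had adjusted p of 0.508, 0.508, 0.454, 0.415, 0.415 and 0.415 in this order. Without the DRlyp/lyp day 50 pool 5 of these lists changed direction, and chemokines then passed in the opposite direction (adjusted p = 0.00704). Cholesterol synthesis genes changed direction without DRlyp/lyp day 20. With both BB day 50 pools left out 4 of these lists changed direction, with adjusted p = 0.0317 for chemokines, 0.678 for complement, 0.639 for interferon-stimulated and 0.725 for macrophage genes. The cause was not tested.

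Over all alternatives 2220 list results stayed the same, 288 were weaker and 27 were reversed. The estimated correlation alone made 119 weaker and left 4 the same. Of named gene results 14791 stayed the same, 532 were weaker, 306 stronger and 183 moved.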

Other observations

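The genes of the first paragraph and all tests of explanations below were chosen after the values were seen, while counts over other assignments were planned before the data were examined.

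In the Flyp/lyp day 30 pool (1 pool on 3 arrays) 7 genes were above the value from strain and day in limma. They were Th (2.18, SE 0.099, adjusted p = 2.72e-06) and Dbh (1.29), enzymes of catecholamine synthesis, the neuronal filament gene Prph (2.42), Sncg (1.79), the monoamine transporter Slc18a2 (0.97), Rab6b (0.87) and Stmn2 (0.77, adjusted p = 0.0447). Th was at least 2.51-fold and Prph at least 4.14-fold higher with the filter value as floor. No list of such genes was tested, and 5 Schwann and neural markers had a mean level of 0.56 and a median of 0.21 in this pool.

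Lymphocyte genes were high in both BB day 50 pools, more so in DR+/+. Lymph node tissue in the islet preparations may contribute, since 10 lymph node markers rose by a median of 1.09 in DRlyp/lyp and 1.86 in DR+/+, against 0.08 in Flyp/lyp and 0.21 in F+/+. Cxcl13 rose by 5.82 and 6.96, Ccl21 by 3.56 and 4.49, Cr2 by 1.66 and 2.95 and Glycam1 by 1.43 and 3.45 in the BB strains, while Madcam1 (0.40 and 0.41), Fcer2 (0.40 and 0.49) and Chst4 (-0.00 and 0.02) had small values. Organised lymphoid tissue within inflamed islets would give the same markers, so these cannot be told apart here. A larger exocrine share was not seen in DRlyp/lyp, where acinar enzymes changed by a median of -0.64 (upper quartile -0.42). In DR+/+ they changed by 0.10 (upper quartile 0.16). The 23 B and T cell markers had lower quartiles of 0.65 in DRlyp/lyp and 0.86 in DR+/+. Acinar mean levels in DR+/+ were 0.25, 0.01, -0.66 and -0.045 over the 4 days, so they rose from day 40 to day 50. A larger exocrine share was therefore not excluded as a part of the DR+/+ rise. The bound on these quartiles replaced an earlier one after these values were seen.

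Interferon-stimulated genes rose more in the DRlyp/lyp than in the DR+/+ day 50 pool, by a median of 0.65 (quartiles 0.29 and 1.13, 33 of 34 genes above 0). Lymphoid tissue of the kind in the DR+/+ pool was excluded as the whole cause, since B cell markers (-1.03, 0 of 9 above 0) and lymph node markers (-0.67) went the other way. Interferon released in insulitis, which per the labels starts in DRlyp/lyp between days 40 and 50, could raise Cxcl9, Ubd and Tap1. A viral or microbial exposure of this pool's rats might do the same and was not tested.

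Exchanging pools between groups gave at least as many genes in 1 of 100 assignments (the real one) for old against young (4889, highest other 3833) and BB against F344 (4802, highest other 4610). For lyp in F344 it was 1 of 35 (38, highest other 1). For lyp in BB it was 35 of 35 (0, highest other 2), and for the slope difference 100 of 100 (0, highest other 4). With a real count of 0 every assignment gives at least as many, so these shares were fixed in advance and decide nothing. On single days each group was 1 pool, so technical arrays were exchanged instead of pools, and the spread between pools was not tested. There were also too few splits, 1 of 10 each. Counts in BB were 5, 5, 30 and 111 and in F344 13, 22, 14 and 21, against 0 for the highest other. For the day 50 departure there were also too few, with 2 of 16 pools at 57 or more and the highest other, DR+/+ day 50, at 92.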
